A study of Homo sapiens with 12 samples.

How the data were processed

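RNA was prepared from 12 cultures of cardiomyocytes, 3 for each of vehicle, ponatinib, metformin and the combination. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, libraries were made with a strand-specific kit (NEBNext Ultra II Directional), and sequencing was done on an Illumina NovaSeq. Per the submitters' processing notes, the tools were STAR and featureCounts and the genome build was GRCh38; versions, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per gene, whole numbers that sum to different totals in each library, with Ensembl gene identifiers and no symbols. Oligo-dT selection leaves out transcripts without a poly(A) tail, and reads that fit several genes (paralogs, pseudogenes such as those of ribosomal proteins) may be lost or split by the counting. Overlapping and antisense genes carry the same doubt, since the strand setting is not given.

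Groups and replicate numbers came from the sample titles and treatments. The titles call the libraries biological replicates without saying what was repeated, so p-values measure the spread between these libraries, which may be partly technical. Totals ran from 7087529 to 9966673 counts, and the median SE of a log2 fold change between 3 and 3 libraries was 0.117 to 0.119 for genes above a mean of 4 log2 CPM. No pair of libraries within a group agreed within sampling noise: the chi-square statistic per degree of freedom over genes with at least 20 counts was 2.7 or more, up to 26.9.

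Of 63140 features, 62541 matched the table that pairs identifiers with symbols. Gene positions and types came from GENCODE release 29 on GRCh38. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16210 genes with 99.7% of counts, 13290 of them protein coding. Counts were normalised by TMM and fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) as 1 quasi-likelihood model over all 12 libraries with group as the only term and 8 residual degrees of freedom. The 5 pairwise contrasts were ponatinib, metformin and combination against vehicle, and combination against ponatinib and against metformin; the interaction was the sixth. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. Levels are TMM-scaled CPM with SD over 3 libraries.

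Before the data were examined, 36 lists were fixed, 26 of pathways and 10 of cell type markers, with 713 genes of which 640 were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 36 lists of a comparison, and again with an estimated correlation; fry was also run and is not used here. Named genes were also chosen by a rule fixed then. For ponatinib against vehicle, metformin against vehicle and combination against ponatinib it took the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 log2 CPM, a symbol that is not a clone name and no overlap between groups. For the other comparisons it took 5 and 5. The rule added the 3 members with the smallest p of each called list, up to 4 members of any list described, members of the target kinase and AMPK lists, and TNNT2, MYH6, MYH7, NPPA and NPPB throughout. Genes on chromosome Y and XIST were not named. Gene lists overlap in places, so the same gene can count in more than 1.

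The response score used log2 CPM with a prior count of 2. Scores of combination and metformin libraries are means over 9 choices. For each of these choices of 1 ponatinib and 1 vehicle library held out, limma ranked genes on the other 2 against 2, and the 200 with the largest moderated statistics gave a signed mean. Overlaps and correlations between comparisons that share libraries were set against 20 simulations of unchanged groups, and 20 with no metformin effect, drawn from the fitted means and dispersions.

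Methods were tested on simulated data. For ponatinib against vehicle with 16210 genes and 200 changed genes in each of 5 simulations, the test recovered 8.8% of genes changed 1.25-fold, 41.6% at 1.5-fold, 66.4% at 2-fold and 88.8% at 4-fold, with 37 false calls in all. A list changed 1.25-fold was called in 5 of 5 simulations, and for metformin against vehicle 1 of 180 unchanged lists was called. These list results hold for simulated data, which need not carry the correlation between genes of real libraries. When the real metformin and vehicle libraries were split in other ways than the real grouping, up to 11 lists were called. The simulated rate of false calls thus cannot be taken as the rate at the preset correlation in the real data. A response planted at 75% was scored at 76%.

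Alternatives planned before the data were examined were DESeq2 size factors, DESeq2 1.42.0 with a Wald test and no independent filtering, no filter on low counts, at least 50 counts in 3 libraries, only the groups compared, the replicate number as a block, glmTreat against a 1.2-fold change, leaving out each library, an estimated correlation for lists, and scores with 50 or 1000 genes. Added after seeing the data were leaving out mitochondrial genes and the 10 most abundant genes, and offsets for each library's loess trend with the length or the GC content of the longest GENCODE transcript, found for 15698 of the 16210 genes.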

Results

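Gene expression was measured by RNA sequencing in ventricular cardiomyocytes derived from human induced pluripotent stem cells, a commercial product sold as Ncyte vCardiomyocytes. Cells were exposed for 24 h, starting on day 7 after seeding, to vehicle (0.1% DMSO), to 1 µM ponatinib, to 1 µM metformin, or to 1 µM ponatinib with 1 µM metformin, called the combination here. Doses and pairs of compounds are as the samples' treatment fields give them. The treatment protocol speaks of a single compound per culture, and metformin is often used at millimolar doses in culture, so the combination and the metformin unit rest on those fields alone. Ponatinib is a multi-kinase inhibitor used in leukaemia with known cardiovascular toxicity, and metformin is a glucose-lowering drug that acts on mitochondria and AMPK signalling. Each of the 4 groups had 3 libraries, and the series title names protection by metformin against ponatinib toxicity as its question. Totals ran from 7087529 to 9966673 counts per library, and 16210 of 63140 features had enough counts to be tested. The titles call the libraries biological replicates without saying what was repeated, so p-values measure the spread between these libraries.

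The first principal component, 31.3% of the variance, separated the 6 libraries with ponatinib (11.35 to 34.25) from the 6 without it (-31.24 to -20.36). Combination libraries were less alike than those of other groups, with a chi-square per degree of freedom between pairs of 8.24 to 26.9, against 2.67 to 6.69 within the other groups. Combination replicate 2 stood apart on the second component (45.19, 13% of the variance, against -21.3 to 12.85 in the other 11 libraries). Its mitochondrial transcripts took 24.38% of counts, against 18.74% to 21.95% elsewhere. It was also the library most depleted of GC-rich transcripts: its trend fell by 0.504 on the log2 scale between transcripts of 38.5% and 61.4% GC. Combination replicate 3 fell by 0.203 over the same span, and the other 10 libraries lay between -0.0232 and 0.177.

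The comparison of ponatinib with vehicle asked what the kinase inhibitor changed. Natriuretic peptide B, NPPB, a marker of myocardial wall stress, fell by 4.31 ± 0.26 on the log2 scale (19.9-fold; SE, n = 3 against 3; adjusted p = 2.3e-10), from 820 ± 111 to 41.3 ± 6.76 CPM (counts scaled to library size, SD, n = 3). The gene lies on chromosome 1 at 11857464 to 11858931 (GRCh38, ENSG00000120937). CSRP3, a Z-disc protein, fell by 3.45 ± 0.22, and NRAP, a protein of nascent myofibrils, fell by 3.44 ± 0.23. MAP2K6, a kinase upstream of p38, rose 18.6-fold (log2 4.22 ± 0.18, adjusted p = 1.14e-12; chromosome 17, 69414698 to 69553861, ENSG00000108984). PHGDH, the first enzyme of serine synthesis, rose 7.41-fold (log2 2.89 ± 0.30). Of 16210 genes, 2438 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 1060 higher and 1378 lower, and 565 of them changed more than 2-fold.

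Myosin heavy chains moved in opposite directions with ponatinib. MYH6, the alpha chain, rose 2.33-fold (log2 1.22 ± 0.09, adjusted p = 6.45e-09), from 5557 ± 191 to 12920 ± 216 CPM (SD, n = 3). MYH7, the beta chain, fell by 1.68 ± 0.16 on the log2 scale (adjusted p = 1.75e-07), from 14650 ± 660 to 4566 ± 248 CPM. These genes are neighbours on chromosome 14 (GRCh38, MYH6 at 23381990 to 23408277 and MYH7 at 23412738 to 23435718) with similar sequences, so reads that fit both could not be assigned with certainty. Cardiac troponin T, TNNT2, did not pass the test (log2 -0.43 ± 0.16, adjusted p = 0.0742), and NPPA passed narrowly (log2 -0.34 ± 0.11, adjusted p = 0.0494), a call lost without any one of the 9 vehicle, ponatinib or metformin libraries (adjusted p = 0.0644 to adjusted p = 0.177). Without combination replicate 1 or 2, TNNT2 passed with the log2 fold change at -0.44 and -0.43. Sarcomere genes fell as a list: 19 of 26 fell, 1 rose and 6 did not pass, or 20 and 2 when adjusted over the list alone. Troponin I, TNNI3, fell by 1.54 ± 0.11 and LMOD2, a thin-filament protein, by 1.73 ± 0.13. Of 20 cardiac stress and hypertrophy genes 14 fell and 6 did not pass over all genes, with RCAN1, a calcineurin target, lower by 2.11 ± 0.15 log2 units. Adjusted over the list alone, 14 fell and 1 rose. Both lists kept their call with an estimated correlation (adjusted p = 0.02 and adjusted p = 0.0141).

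Immediate early genes and other targets of ERK signalling fell the furthest of the lists (median log2 fold change -1.40). Of 26 measured, 23 fell and 3 did not pass, and 25 fell when adjusted over the list alone. ETV5, a transcription factor induced by fibroblast growth factor and ERK, fell by 2.38 ± 0.14, PHLDA1 by 1.47 ± 0.13 and JUN by 1.51 ± 0.14. Cell cycle genes moved the other way: 25 of 27 rose and none fell, and all 27 rose when adjusted over the list alone (median 0.74). TOP2A, which untangles DNA before mitosis, rose 2.03-fold (log2 1.02 ± 0.09), and KIF11 and CENPF, needed for the spindle and kinetochore, rose 2.02-fold and 1.71-fold. Both lists passed with an estimated correlation (adjusted p = 0.0141 for each).

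**Figure D1:**
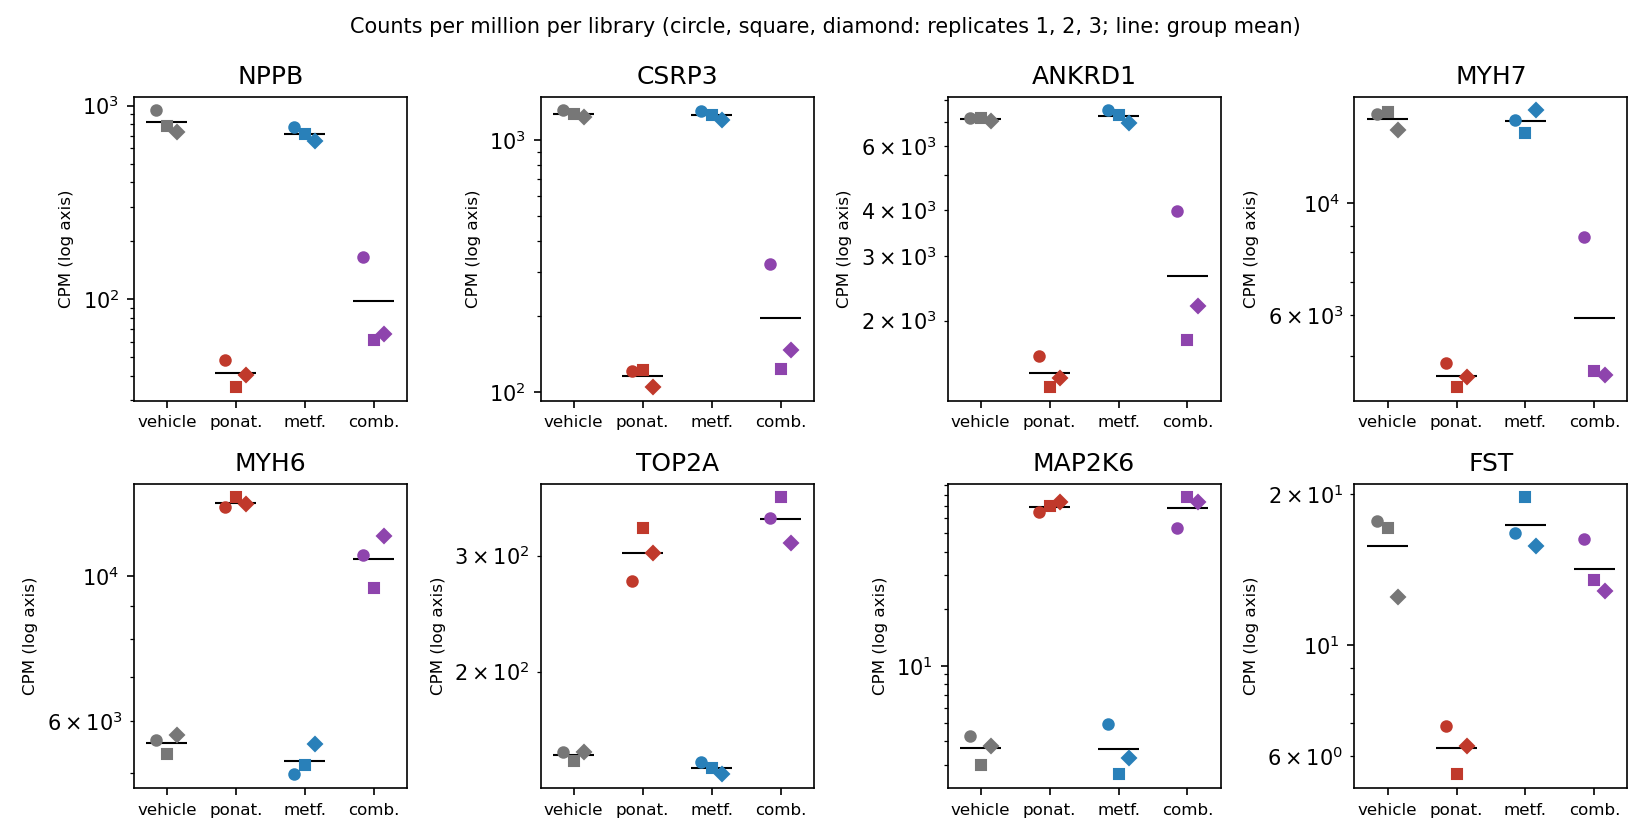
Level in CPM (log axes that differ between panels) of 8 genes in each library, by group, with a line at the group mean of 3 libraries. NPPB was near 820 CPM in vehicle and near 41.3 CPM with ponatinib, and combination replicate 1 (circle) had the highest NPPB, CSRP3, ANKRD1 and MYH7 of the combination libraries.

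Several metabolic and matrix lists were lower with ponatinib by the camera test at its preset correlation but not with an estimated one. Of 48 nuclear-encoded genes of oxidative phosphorylation, 23 fell and none rose (31 fell adjusted over the list alone), with NDUFA1 of complex I lower by 0.59 ± 0.11 log2 units (adjusted p = 0.133 for the list with an estimated correlation). Of 25 glycolysis genes 16 fell and 2 rose (17 and 2 adjusted over the list alone); LDHA, lactate dehydrogenase, fell by 0.96 ± 0.11 and HK2, hexokinase, by 0.98 ± 0.13 (adjusted p = 0.151 for the list with an estimated correlation). Of 22 targets of YAP and SRF, 14 fell (15 fell and 1 rose adjusted over the list alone), among them ANKRD1 by 2.31 ± 0.19 and CCN1 by 1.77 ± 0.16 (adjusted p = 0.112 for the list with an estimated correlation). Of 25 extracellular matrix and TGF-beta genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone), with THBS1, a matrix glycoprotein, lower by 2.00 ± 0.18 (adjusted p = 0.386 for the list with an estimated correlation). In the integrated stress response list 11 of 33 rose and 5 fell (14 and 5 adjusted over the list alone): PHGDH rose, while PPP1R15A, a phosphatase subunit, fell by 0.92 ± 0.11 and ATF3, a transcription factor, by 1.21 ± 0.18 (adjusted p = 0.664 for the list with an estimated correlation). The preset call of this list was lost without vehicle replicate 2 or 3 (adjusted p = 0.0504 and adjusted p = 0.152).

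Further lists passed only at the preset correlation. Unfolded protein response (7 of 22 fell), hypoxia response (7 of 19 fell, 1 rose), heat shock (3 of 20 fell) and fatty acid uptake and oxidation (6 of 30 fell) were lower; adjusted over the list alone, 9, 9, 3 and 6 fell and 1 hypoxia gene rose. With an estimated correlation their values were adjusted p = 0.386, adjusted p = 0.181, adjusted p = 0.386 and adjusted p = 0.181. HSPA5, the endoplasmic reticulum chaperone BiP, fell by 0.68 ± 0.16 and HSPB1, a small heat shock protein, by 1.15 ± 0.11. The kinases that ponatinib is known to inhibit did not move as a list (adjusted p = 0.146), although 6 of 14 fell, including KDR by 0.69 ± 0.13 and FGFR1 by 0.32 ± 0.10; 6 fell adjusted over the list alone. The FGFR1 call was lost without vehicle replicate 2 or any one of the ponatinib replicates. Among AMPK components, PRKAA2, a catalytic subunit, fell by 0.71 ± 0.11 and the transporter SLC29A4 rose by 0.49 ± 0.16 log2 units, 2 of 14 measured, and the same number adjusted over the list alone; the list was not called (adjusted p = 0.787; median 0.05, with a test pointing down). The SLC29A4 call was lost in 10 of 12 fits that left out a library. Ion channel, cholesterol synthesis, fatty acid synthesis, NRF2, p53, BCL2 family, PI3K and FOXO, autophagy, NF-kB, interferon, mitochondrially encoded, pluripotency and endoderm lists were not called (adjusted p = 0.103 to adjusted p = 0.915), with the mitochondrially encoded list called lower without ponatinib replicate 3 (adjusted p = 0.0193). Without vehicle replicate 3 the fatty acid oxidation list was not called (adjusted p = 0.0688).

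Markers of other cell types were measured beside these lists. Epicardial markers were lower (4 of 7 fell, median -1.13; adjusted p = 0.0143 with an estimated correlation), led by the keratins KRT18 and KRT8, lower by 1.47 ± 0.10 and 1.36 ± 0.11. Neural markers were lower (2 of 6 fell, adjusted p = 0.0454 with an estimated correlation); the intermediate filament NES, at 951 CPM in vehicle, fell by 1.21 ± 0.14. Endothelial (4 of 9 fell) and smooth muscle (4 of 12 fell, 1 rose) markers passed only at the preset correlation (adjusted p = 0.345 and adjusted p = 0.106 with an estimated one). Fibroblast markers were not called (adjusted p = 0.888), and their median (-0.19) and test differed in sign. Ventricular markers were split, 5 of 10 lower and 4 higher, and pacemaker-like markers had 2 of 8 higher, VSNL1 by 5.05-fold. Both of these lists also passed only at the preset correlation (adjusted p = 0.345 and adjusted p = 0.106 with an estimated one). Atrial markers were not called (adjusted p = 0.133). Adjusted over the list alone, 4 epicardial, 3 neural, 7 endothelial and 4 smooth muscle markers fell. The endothelial list was not called without vehicle replicate 1 (adjusted p = 0.0781).

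Libraries of both groups did not overlap for 35.5% of genes, against 10% by chance. Leaving out ponatinib replicate 2 lowered the number of called genes to 1532.

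The comparison of metformin with vehicle asked what metformin did alone. No gene passed edgeR's test, 485 had an unadjusted p under 0.05, and DESeq2 also called 0. Cardiac genes lay near their vehicle level: log2 fold changes were -0.20 ± 0.22 for NPPB (95% interval -0.71 to 0.31), -0.01 ± 0.16 for MYH7, -0.09 ± 0.09 for MYH6, -0.08 ± 0.11 for NPPA and 0.07 ± 0.16 for TNNT2 (SE, n = 3 against 3). Libraries of both groups did not overlap for 9.7% of genes, against 10% by chance. The camera test called 3 lists lower at its preset correlation, with none of their genes passing over all genes or adjusted over the list alone. These were nuclear-encoded oxidative phosphorylation (median -0.09), NF-kB and inflammation (-0.27) and autophagy and lysosome genes (-0.08), at adjusted p = 0.877, adjusted p = 0.673 and adjusted p = 0.963 with an estimated correlation. AMPK components were not called (adjusted p = 0.838; median 0.02, with a test pointing down). The count of 3 lists became 5 without vehicle replicate 1 or 2 or combination replicate 2, 7 without metformin replicate 2 and 8 without metformin replicate 1. Without vehicle replicate 1 just oxidative phosphorylation was kept of the 3, and the 4 gained were higher: endothelial (median 0.723, against 0.214 with all libraries), fibroblast (0.215), matrix (0.177) and YAP and SRF genes (0.087). The matrix list was also called higher without metformin replicate 3 (0.069), but lower without vehicle replicate 3 (-0.162) or metformin replicate 2 (-0.177). Oxidative phosphorylation was not called without vehicle replicate 3, NF-kB without vehicle replicate 1 or metformin replicate 3, and autophagy without any one of 5 libraries.

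The combination against vehicle asked what remained of the ponatinib change when metformin was present. MAP2K6 was 18.3-fold higher (log2 4.19 ± 0.18) and PHGDH 5.82-fold higher (log2 2.54 ± 0.30). NRAP fell by 3.36 ± 0.23, NPPB by 3.09 ± 0.24, CSRP3 by 2.69 ± 0.22 and MYH7 by 1.30 ± 0.16, while MYH6 rose 1.91-fold (log2 0.93 ± 0.09). TNNT2 fell by 0.56 ± 0.16 (adjusted p = 0.0248), a call lost without vehicle replicate 2 or 3 or combination replicate 3 (adjusted p = 0.0932, adjusted p = 0.0775 and adjusted p = 0.0519). Without combination replicate 2 the TNNT2 fall was 0.31 (adjusted p = 0.0299). NPPA did not pass (log2 -0.12 ± 0.11, adjusted p = 0.579), a value that rests on combination replicate 2, without which NPPA was called lower (log2 -0.31, adjusted p = 0.00992). In all 1719 genes were called, 835 higher and 884 lower. Of these, 1301 were also called with ponatinib alone and all 1301 in the same direction, 619 higher and 682 lower. Independent lists of these sizes would share 54.6 higher and 75.2 lower genes. Data simulated with the ponatinib effect in both groups and no metformin effect shared 2636 genes on average, with 3582 and 3570 called. Part of the excess over independence may come from the shared vehicle libraries.

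All 27 cell cycle genes rose with the combination (27 adjusted over the list alone), TOP2A by 2.28-fold and PCNA, the replication clamp, by 2.12-fold. Of 26 ERK target genes 19 fell (22 adjusted over the list alone), with ETV5 lower by 1.81 ± 0.14. Sarcomere (16 of 26 fell, 1 rose; 20 and 1 adjusted over the list alone) and cardiac stress genes (11 of 20 fell; 14 fell and 1 rose adjusted over the list alone) were lower too. These lists, with epicardial (4 of 7 fell) and neural markers (2 of 6 fell), are the 6 of 11 called lists that passed with an estimated correlation. Nuclear-encoded oxidative phosphorylation was not called (3 of 48 fell over all genes and 3 adjusted over the list alone, adjusted p = 0.0748), except without vehicle replicate 1 (adjusted p = 0.00459) or combination replicate 2 (adjusted p = 0.00104). The 11 lists became 19 without combination replicate 2. The 1719 became 1066 without vehicle replicate 1, 2843 without combination replicate 1 and 907 in a fit of these groups alone. With an offset for each library's GC trend 1664 genes were called, of which 1339 were among the 1719.

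**Figure D2:**
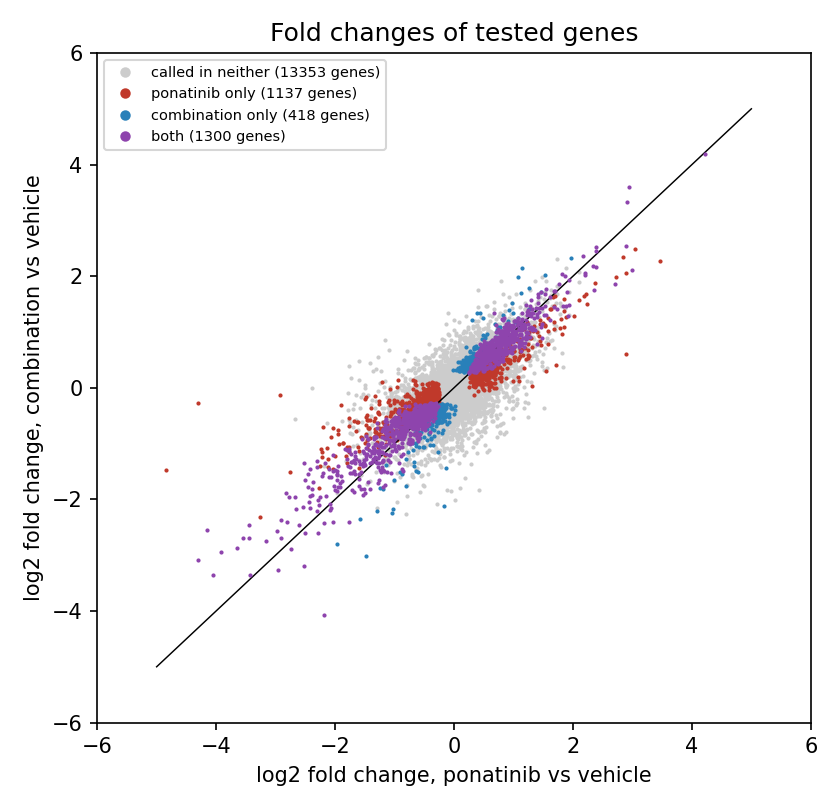
Log2 fold change of the tested genes with the combination (vertical axis) against ponatinib alone (horizontal axis), both relative to the same vehicle libraries, with the line of equality. Genes on chromosome Y and XIST are left out, 1 gene lies outside the axes, and 1300 genes called in both comparisons are drawn in purple; the slope over all 2438 genes called with ponatinib was 0.768.

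The combination against ponatinib asked what metformin changed in the presence of ponatinib. A single gene passed: FST, which encodes follistatin, an activin-binding protein (chromosome 5, 53480409 to 53487134, GRCh38). It was 2.26-fold higher in the combination (log2 1.18 ± 0.18, 95% interval 0.76 to 1.60, adjusted p = 0.0258), at 14.2 ± 1.86 CPM against 6.24 ± 0.684 with ponatinib and 15.7 ± 2.87 in vehicle (SD, n = 3), and higher in 3 of 3 libraries than in any ponatinib library (ENSG00000134363). Across alternatives its adjusted p ran from 1.79e-06 to 0.389, and the call was lost without any one of the ponatinib libraries, metformin replicate 1 or combination replicate 3. NPPB (log2 1.22 ± 0.24, adjusted p = 0.0897), ANKRD1 (0.88 ± 0.18, adjusted p = 0.0897) and CSRP3 (0.76 ± 0.21, adjusted p = 0.155) had positive fold changes that did not pass. MYH7 (0.38 ± 0.16, adjusted p = 0.356), MYH6 (-0.28 ± 0.09, adjusted p = 0.242), NPPA (0.22 ± 0.11, adjusted p = 0.456) and TNNT2 (-0.13 ± 0.16, adjusted p = 0.781) did not pass either.

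The combination libraries differed from each other in these genes. Replicate 1 had 164 CPM of NPPB, against 61.3 and 65.4 in replicates 2 and 3, and 8564 CPM of MYH7, against 4672 and 4581. Without replicate 1 the log2 fold changes fell to 0.02 for MYH7, 0.22 for CSRP3, 0.46 for ANKRD1 (adjusted p = 0.0111) and 0.62 for NPPB (adjusted p = 0.00968). Without replicate 2, ANKRD1 (log2 1.10, adjusted p = 8.28e-05), NPPB (log2 1.46, adjusted p = 0.000624) and CSRP3 (log2 1.01, adjusted p = 0.00244) passed, with NPPA at 0.03 and TNNT2 at 0.11.

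The camera test called 12 lists higher in the combination than in ponatinib at its preset correlation, and none with an estimated correlation (adjusted p = 0.591 to adjusted p = 0.602). No member of any of them passed over all genes. Nuclear-encoded oxidative phosphorylation had a positive fold change in 43 of 48 genes (median 0.23; 18 rose adjusted over the list alone), with UQCRB of complex III at 0.40 ± 0.09. The mitochondrially encoded list was positive in 13 of 13 (median 0.21; 0 adjusted over the list alone), in a group whose replicate 2 had the highest mitochondrial share. Cardiac stress (median 0.22; 4 rose adjusted over the list alone), ERK targets (0.22; 4), YAP and SRF targets (0.165; 5), matrix genes (0.26; 4) and sarcomere genes (0.14; 6 rose and 1 fell) had positive medians. Endothelial (0.55), fibroblast (0.32), epicardial (0.30), smooth muscle (0.16) and heat shock (0.12) lists did as well. Without combination replicate 1 the sarcomere (median 0.033), ERK (0.073), YAP and SRF (0.06), smooth muscle and endothelial lists were no longer called, and without combination replicate 2 the heat shock list (0.002). Without ponatinib replicate 2 the ERK, heat shock, fibroblast, smooth muscle, endothelial and epicardial lists were not called, nor smooth muscle without ponatinib replicate 1 or fibroblast without combination replicate 3. Cell cycle genes were not called (median 0.09, adjusted p = 0.0866), except without ponatinib replicate 2 or combination replicate 3.

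By DESeq2's Wald test 106 genes were called in this comparison, 95 of them higher in the combination, and by edgeR 1939 genes had an unadjusted p under 0.05. Counts were 593 without combination replicate 1, 102 without combination replicate 2 and 0 without combination replicate 3, without metformin replicate 1 or without any one of the ponatinib replicates. The 593 followed GC content: the median was 42.8% for the 244 higher genes and 62.8% for the 349 lower ones, against 48.4% over all tested genes. With an offset for each library's GC trend, 34 genes were called without replicate 1 and 87 without replicate 2.

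**Figure D3:**
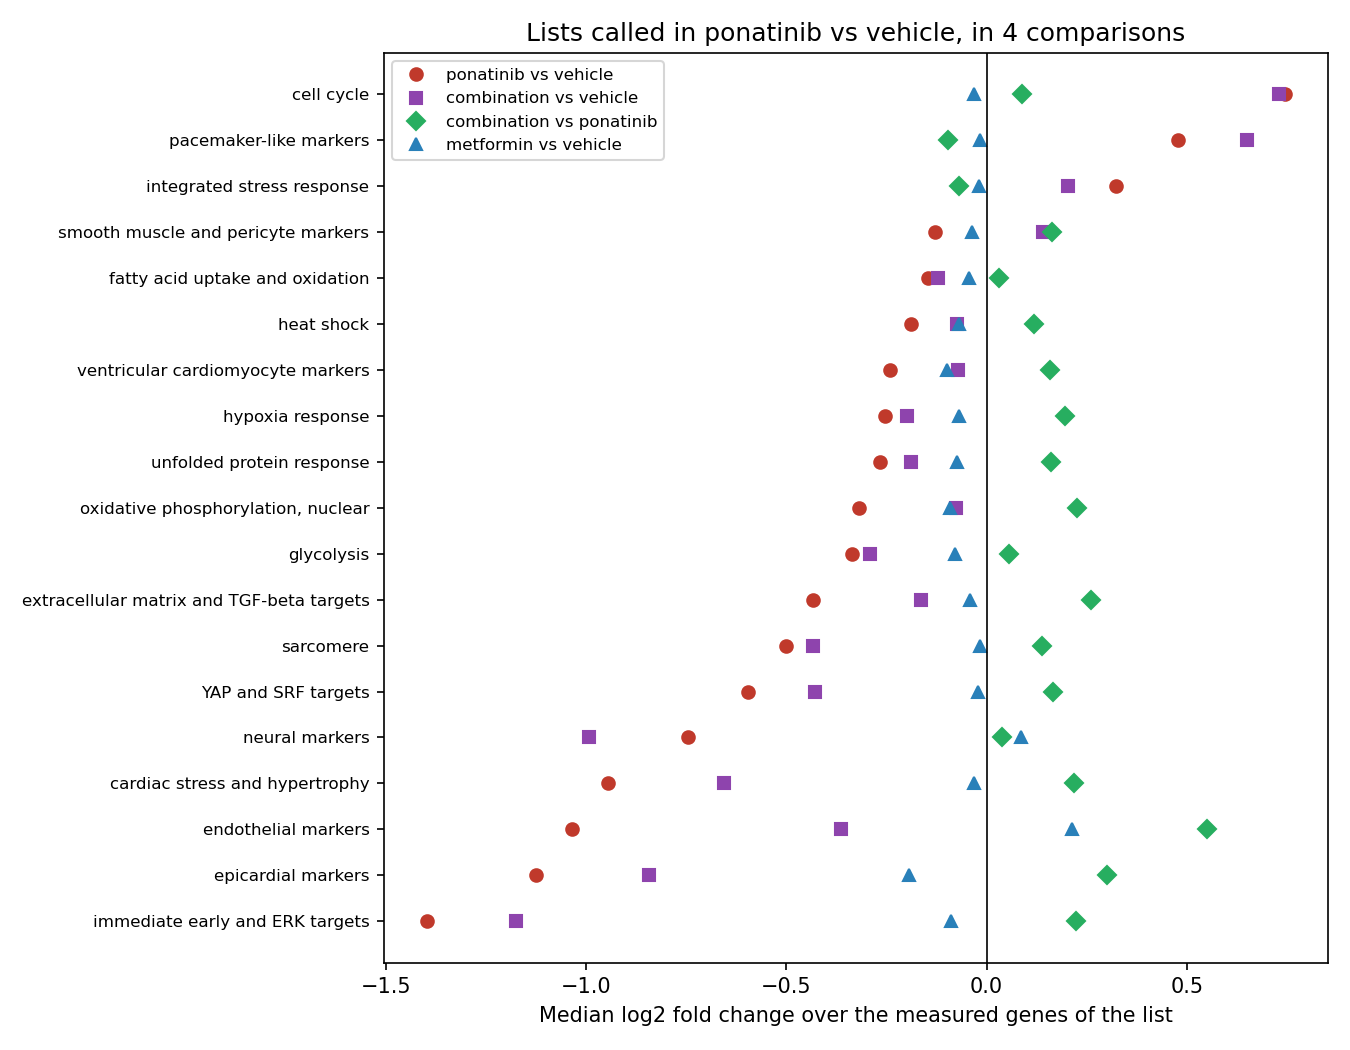
Median log2 fold change over the measured genes of each list called in ponatinib against vehicle, in 4 comparisons (symbols). Cell cycle genes had medians of 0.74 with ponatinib and 0.73 with the combination, and ERK targets -1.40 and -1.18.

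A score built from the 200 genes that best separated ponatinib from vehicle, with the libraries it scored held out, placed vehicle at 0% and ponatinib at 100%. Ponatinib libraries were scored against the mean of the held-out ponatinib libraries, so their mean is 100% by construction and their values are not computed quite as those of the other groups. Combination libraries scored 63.4%, 94.1% and 87.4% (mean 81.6 ± 16.1%, SD, n = 3; 90.7% without replicate 1), and ponatinib libraries 94.7% to 104%. Averaged over held-out choices, every combination library lay below every ponatinib library. Permuting these scores gives a p of 0.1 (two-sided), the smallest that 3 against 3 allows. It is not an exact p, since scores of the 2 groups were not computed alike. Replicate 2 at 94.1% was just under the lowest ponatinib library at 94.7%, and its score ran from 87.5% to 104% over the 9 choices. Metformin libraries scored -4.5%, 0.304% and 2.64% (mean -0.519 ± 3.64%). Across the 2438 genes called with ponatinib, the combination retained a slope of 0.768 on the ponatinib fold changes. Simulated data with no metformin effect gave a slope of 0.904 (0.891 to 0.916 over 20 simulations), below 1 because genes were chosen on the ponatinib libraries. The simulation drew genes independently and called 3582 genes with ponatinib instead of 2438, so its range is too narrow as an error. It also took the observed group means, noise included, as the true ones, and left out the wider spread between combination libraries. Its slope, and its correlation of 0.880 given below, may thus be too high, and the gap to the observed values overstated. Fold changes of combination against vehicle correlated with those of ponatinib across genes (r = 0.784; genes are not independent replicates), against 0.505 in simulated unchanged groups and 0.880 in data simulated with no metformin effect, with a covariance of 0.188 against 0.0432 and 0.308. Metformin and ponatinib fold changes correlated at r = 0.341, against 0.501 in unchanged groups and 0.243 with no metformin effect, with a covariance of 0.0526 against 0.0436 and 0.0429. Fold changes of combination against ponatinib correlated at r = -0.444 with those of ponatinib against vehicle, against -0.494 in unchanged groups and -0.237 with no metformin effect, with a covariance of -0.0738 against -0.0420 and -0.0404.

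**Figure D4:**
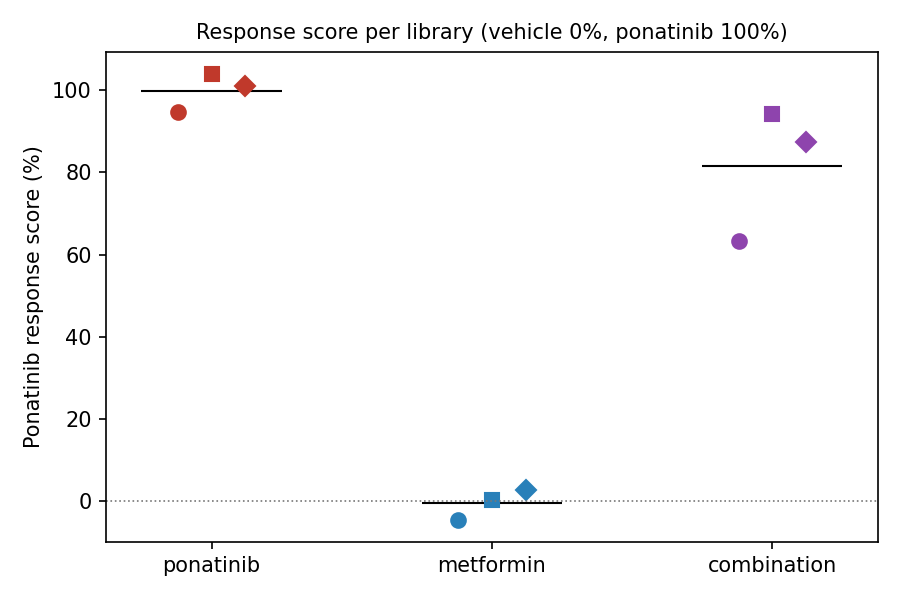
Ponatinib response score in percent for each ponatinib, metformin and combination library, with a line at the mean of 3 libraries and a dotted line at the vehicle level of 0%. Combination replicate 1 (circle) scored 63.4%, and the other combination libraries 94.1% and 87.4%.

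The combination was also set against metformin alone, which asked what ponatinib did in the presence of metformin. MAP2K6 was 19.1-fold higher (log2 4.25 ± 0.19) and PHGDH 6.06-fold higher. NRAP fell by 3.44 ± 0.23, NPPB by 2.89 ± 0.24, MYH7 by 1.29 ± 0.16 and TNNT2 by 0.63 ± 0.16; MYH6 rose 2.03-fold, and NPPA did not pass (log2 -0.04 ± 0.11, adjusted p = 0.89). Without combination replicate 2 the log2 fold changes were -0.39 for TNNT2 (adjusted p = 0.00796) and -0.23 for NPPA (adjusted p = 0.0787). In total 1642 genes were called, 824 higher and 818 lower. Cell cycle genes rose (26 of 27, and 26 adjusted over the list alone), and ERK targets (18 of 26), sarcomere (15 of 26, with 1 higher), cardiac stress (10 of 20) and neural genes (3 of 6) fell; these 5 of 11 called lists passed with an estimated correlation. Adjusted over the list alone, 21 ERK targets, 19 sarcomere, 14 cardiac stress and 3 neural genes fell. Interferon response genes passed at the preset correlation only (3 of 15 rose, 5 adjusted over the list alone; adjusted p = 0.197 with an estimated correlation), with IFIT1, an antiviral RNA-binding protein, higher by 2.62-fold (log2 1.39 ± 0.14). Without metformin replicate 3 the interferon list was not called (adjusted p = 0.0585), and without combination replicate 2 the 11 lists became 17. The count of genes was 2927 without combination replicate 1, 1086 without metformin replicate 1, 1014 without metformin replicate 2 and 1001 in a fit of these groups alone. With the offset for GC trends it was 1595, of which 1310 were among the 1642.

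The interaction asked whether metformin's effect differed with and without ponatinib. No gene passed edgeR's test, 1443 had an unadjusted p under 0.05, and DESeq2 called 2. The smallest edgeR adjusted p was 0.49. NPPB had an interaction of 1.42 ± 0.33 log2 units (adjusted p = 0.49), ACTA2, smooth muscle actin, 0.60 ± 0.12 (adjusted p = 0.49), MYH7 0.39 ± 0.22, MYH6 -0.19 ± 0.13, NPPA 0.30 ± 0.16 and TNNT2 -0.20 ± 0.22. Single libraries carried several of these: MYH7 was 0.03 without combination replicate 1, and NPPA 0.11 and TNNT2 0.04 without combination replicate 2. Without combination replicate 1 the test called 39 genes, and without combination replicate 2 it called 3. NPPB was among those called in both (log2 0.81, adjusted p = 0.0326, and log2 1.66, adjusted p = 0.0113). The camera test called 14 lists, all with positive medians, at its preset correlation and none with an estimated correlation (adjusted p = 0.399 to adjusted p = 0.698). Without ponatinib replicate 2 it called 9 lists. Of the 14, 11 lost their call in at least 1 fit that left out a library; oxidative phosphorylation, epicardial and cardiac stress lists kept theirs in all 12. The matrix median was -0.03 without vehicle replicate 1 (adjusted p = 0.948), sarcomere 0.036 and YAP and SRF 0.094 without combination replicate 1, and unfolded protein response 0.049 and heat shock 0.095 without combination replicate 2.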

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

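The tests of combination replicate 1, mixed RNA, the cardiomyocyte share and a few genes taking most of the counts were chosen after their results were seen, and the GC content, transcript length and abundant gene settings were added after the data were seen. The interaction is given here because the camera test called 14 lists for it at its preset correlation and none with an estimated correlation (adjusted p = 0.399 to adjusted p = 0.698). Median interactions in log2 units were 0.335 for nuclear-encoded oxidative phosphorylation, 0.459 for epicardial, 0.273 for ventricular, 0.2 for atrial and 0.105 for smooth muscle markers, 0.317 for ERK targets, 0.253 for matrix genes, 0.247 for cardiac stress, 0.23 for the unfolded protein response, 0.204 for mitochondrially encoded genes, 0.199 for heat shock, 0.172 for sarcomere, 0.17 for YAP and SRF targets and 0.141 for fatty acid oxidation. Only oxidative phosphorylation, epicardial and cardiac stress lists kept the call whichever library was left out. The matrix median turned to -0.03 without vehicle replicate 1, sarcomere fell to 0.036 and YAP and SRF to 0.094 without combination replicate 1, and unfolded protein response to 0.049 and heat shock to 0.095 without combination replicate 2, each with the call lost. Among 100 splits, the real grouping included, 8 gave at least 14 lists (highest other 17), so chance is not excluded for the count of lists. The real count of 0 genes is reached by all 100 by construction (highest other 10), which tests nothing.

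The 6 libraries of each pairwise comparison can be split in 10 ways, the real grouping included, too few for a share under 0.05. Each other split mixed libraries of both real groups in unequal numbers. Part of a real difference thus stayed between the sides of a split, and the rest added to the spread within them. Counts from other splits need therefore not be those of unchanged libraries, for genes or for lists. As counts of genes, 1 of 10 splits, the real one, reached 2438 with ponatinib (highest other 0), 1 reached 1719 with the combination against vehicle (0), 1 reached 1642 against metformin (0) and 1 reached the single gene against ponatinib (0). For metformin the real count is 0, which all 10 reach by construction (highest other 2). The counts of lists also include the real grouping. Ponatinib's 19 lists were reached by 1 split (highest other 15), the combination's 11 by 6 (highest other 18), the 12 against ponatinib by 2 (highest other 13), the 11 against metformin by 5 (highest other 15) and the 3 of metformin by 8 (highest other 11).

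Oxidative phosphorylation genes had higher values in the combination than in ponatinib (median 0.226, SE 0.025 over genes). An offset for transcript length left 0.239 and one for GC content 0.208, and without combination replicate 2 the median was 0.15, each with the preset call retained. Combination replicate 2 alone could thus not account for the whole shift. The offsets used the longest annotated transcript of each gene, which need not be the one expressed. They therefore cannot exclude a bias with length or GC content. With an estimated correlation the call was lost (adjusted p = 0.591), so a general shift between libraries stays open beside an effect of metformin, which is a hypothesis here.

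Combination libraries lay nearer to vehicle than ponatinib libraries did on the response score, by a mean that rests largely on replicate 1 (63.4%). Replicates 2 and 3 averaged 90.8%, with replicate 2 (94.1%) within 1 SD of the lowest ponatinib library (94.7%, SD 4.83%) and replicate 3 (87.4%) below it, so whether the shift belongs to the group or to replicate 1 cannot be told apart with 3 libraries. The way back from ponatinib to vehicle was measured over the genes called with ponatinib, 23 ERK targets and 25 cell cycle genes. They were chosen for their difference between these same libraries, which can make other libraries look partly returned. In replicate 1 ERK targets lay at a median of 23% (quartiles 19.1% to 30.8%) and cell cycle genes at -27.9% (-47.7% to -11.8%). In replicates 2 and 3 cell cycle genes lay at -25.4% (-58.5% to -2.25%) and 10.7%, and ERK targets at -1.86% and 3.32%. Vehicle RNA mixed into replicate 1 would move both groups towards vehicle, but the level of its cell cycle genes without mixing is unknown and spreads widely between the other libraries, so mixing and a true difference cannot be told apart. A lower ponatinib exposure in that culture may be involved and was not tested.

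Cell cycle genes rose with ponatinib. A lower share of cardiomyocytes would raise markers of the other cell types alike only if ponatinib did not itself change those markers. That was not tested, and cardiomyocytes may express some of them. The epicardial median was -1.13 and the neural and endothelial medians were -0.745 and -1.036. The median of 2 pluripotency markers, which were not called, was 0.231. These values do not decide on a change in the share of cardiomyocytes. A few genes taking most of the counts would scale all other genes of a library alike. The median of the list instead lay 0.732 above that of all tested genes (SE 0.065 over genes of the list, not over libraries). Leaving out the mitochondrial and 10 most abundant genes before normalisation moved almost nothing (2437 genes called, 2432 of them among the 2438), so it tested nothing. Whether the rise lies in cardiomyocytes or in a minor cell type was not tested.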

How the results depend on the processing

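Offsets for GC content and length, and leaving out abundant genes, were chosen after the data were seen; the other alternatives were planned. Of 19475 values of named genes across alternatives, 18699 kept their side of the threshold (and their direction, where called), 508 lost and 268 gained a call, and 0 reversed. Among 4710 values of lists, 4369 kept theirs, 148 lost and 189 gained a call, and 4 reversed: the matrix list for metformin became called lower without vehicle replicate 3 (median -0.162) and without metformin replicate 2 (-0.177), against 0.177 and called higher without vehicle replicate 1, and the integrated stress response became called higher without combination replicate 1 against ponatinib (0.134) and in the interaction (0.117), against -0.193 and -0.181 and called lower without combination replicate 2. The cause was not tested except where stated.
With an estimated correlation, 6, 0, 6, 0, 5 and 0 lists were called for ponatinib, metformin and combination against vehicle, combination against ponatinib, against metformin, and the interaction. Against a minimum fold of 1.2, 1132 genes were called with ponatinib, 760 with the combination, 741 against metformin and 0 against ponatinib, since the question is stricter. With only the groups compared, 3472 genes were called with ponatinib, more than the 2438 from all libraries. The fits gave 907 for the combination, 1001 against metformin, 0 against ponatinib, and 8 lists for metformin. The shared spread includes the combination libraries, which were less alike than the others. Without combination replicate 1 or 2, ponatinib against vehicle gave 3014 and 3308 genes. P-values from the shared spread may thus be too high for ponatinib against vehicle and too low for comparisons with the combination. For the combination against ponatinib (1 gene) the counts were 229 with no low-count filter, 0 at 50 counts, 106 by DESeq2, 3 with the GC offset, 2 with GC and length offsets, and 34 or 87 with the GC offset and replicate 1 or 2 left out. With no low-count filter 19 lists were called for it, 19 for the combination against vehicle and 42 genes for the interaction; DESeq2 called 2 for the interaction. Genes called in both ponatinib and the combination numbered 764 at an adjusted p of 0.01. Those called with ponatinib and in the opposite direction in the combination against ponatinib were 0 at that level and 91 by DESeq2, against 1. These comparisons share the ponatinib libraries, which pushes fold changes to opposite signs. In the simulated data DESeq2 made 60 false calls, against 37 by edgeR.
Leaving out 1 library gave 1532 (ponatinib replicate 2) to 3308 (combination replicate 2) genes with ponatinib, 1066 to 2843 with the combination, 0 to 593 against ponatinib, 1014 to 2927 against metformin, 0 for metformin, and 0 to 39 for the interaction. Lists ran from 17 to 20, 9 to 19, 8 to 15, 9 to 17, 2 to 8 and 9 to 19 in that order. The score ran from 75.4% to 90.7%, and with 50 genes, 1000 genes or DESeq2 size factors it was 81.7%, 80.5% and 81.4%.
The replicate numbers did not pair the libraries: 18 same-numbered pairs across groups had a mean correlation of -0.007 (-0.101 to 0.104), 1 above 0.1, and 3 of 12 libraries correlated best with their own number. With the replicate block 2 genes were called for the combination against ponatinib and 2265 for ponatinib against vehicle. Small effects were mostly missed at this depth with 3 libraries per group: 8.8% of genes with the smallest change planted in simulated data were recovered for ponatinib against vehicle. Depth was not varied, and the number of libraries only by leaving out 1 at a time.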

Other observations

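Ribosomal protein genes were gathered by symbol after the data were seen, together with their close paralogs, and their tests were chosen then. Of 82 genes, 52 fell with ponatinib and none rose (median log2 fold change -0.336; adjusted p = 0.0112 with an estimated correlation), among them RPL41 by 0.62 ± 0.09 and RPS29 by 0.96 ± 0.14. In the combination 5 fell against vehicle (median -0.0887, adjusted p = 0.538 with an estimated correlation). Against ponatinib 79 of 82 had a positive fold change (median 0.266, adjusted p = 0.0087 with an estimated correlation), although no single gene passed with all libraries (25 rose without combination replicate 1 and 21 without replicate 2); RPS29 had 0.72 ± 0.15 (adjusted p = 0.0897). The interaction median was 0.366 (80 of 82 positive, adjusted p = 0.00578 with an estimated correlation). Metformin alone had a median of -0.101, with 68 of 82 negative, which is part of that interaction. By the camera test this gave adjusted p = 1.83e-08 at the preset correlation and adjusted p = 0.346 with an estimated one. The median against ponatinib was 0.271 with the length offset, 0.272 with the GC offset and 0.241 with both, and 0.287, 0.259 and 0.253 without combination replicates 1, 2 and 3. Since the offsets used the longest annotated transcript of each gene, a bias with the length or GC content of expressed transcripts is not excluded. Many of these genes have near-identical pseudogenes, and they were picked after seeing them, so the p-values are not independent evidence.

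Combination replicate 2, with a difference of -0.504 on the log2 scale between transcripts of high and low GC content, also had the largest mitochondrial share, and combination replicate 3 had the next most negative trend (-0.203) while vehicle libraries lay between -0.0232 and 0.177 and combination replicate 1 had 0.0209.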
